A study of Arabidopsis thaliana with 8 samples.

How the data were processed

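Steady-state mRNA and ribosome-protected mRNA were measured in Arabidopsis thaliana seedlings of the Col-0 accession, grown for 4 days in darkness on Murashige-Skoog medium and collected with or without 4 h of white light. Per the labels, steady-state mRNA was purified with a commercial mRNA kit and fragmented, ribosome-protected mRNA was obtained by RNase I digestion of polysome extracts followed by SDS and phenol extraction, and libraries were prepared after a published ribosome profiling protocol. The 8 libraries form 4 groups of 2, with the group and the repeat number taken from the labels.

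The deposited tables give, per the file headers, read counts for each gene in the 5′ untranslated region, the coding sequence (CDS) and the 3′ untranslated region, with 1 gene model per locus. The counts are whole numbers that were not normalized by the authors. Per the submitters' processing notes the build was TAIR 10. The aligner, the counting tool, the use of strand and the treatment of reads that map to several places are not given in the sources used here, so near-identical gene copies and overlapping or antisense genes are reported with that limit. The tables also hold RPKM values, which per the file headers the authors computed for each region. Reads divided by length and by RPKM gave 1 constant per library, equal to the sum of its 3 count columns, and the RPKM of coding sequences served only for that check. The other 16 columns of RPKM, for untranslated regions, were not used. The first repeat stands in a table of the whole genome and the second in a table of its own.

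All tests used the CDS counts of 27415 genes, of which 3938 had no CDS read in any library. After edgeR's filterByExpr, 19823 genes were tested. Counts were scaled by TMM, whose factors ran from 0.824 to 1.26, and fitted with edgeR's quasi-likelihood model (edgeR 4.0.16, R 4.3.3) with 1 mean per group over all 8 libraries, so that the groups shared an estimate of the spread. The contrasts were light against dark in mRNA, light against dark in ribosome-protected mRNA, their difference (the interaction, which tests translational efficiency in 1 model over both kinds of library), and ribosome-protected against steady-state mRNA in the dark and after light. Tests were two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Fold changes are on the log2 scale with standard errors from the fit. Values per library are read counts scaled to library size (CPM), and logarithms used a prior count of 2. An exact permutation of 2 against 2 libraries cannot give a p below 0.333, so single values were not tested that way.

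The design, the tests, 24 gene lists with 580 members given by locus identifier, the rule for named genes and most other settings were fixed before the data were examined. The lists covered light-harvesting proteins, nuclear photosystem and electron transport subunits, chlorophyll synthesis, the Calvin cycle, the flavonoid pathway, photoreceptors, light signalling factors, the clock, cytosolic and plastid ribosomal proteins, translation factors, expansins and XTHs, auxin response, gibberellin and brassinosteroid, ethylene and the apical hook, seed reserves, heat shock and oxidative stress, the cell cycle, root markers, stomatal lineage markers, conserved peptide uORF genes, miRNA targets, and plastid- and mitochondrion-encoded genes. Each list with at least 5 tested members was compared with all other genes by camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, and again with an estimated correlation. The uORF list had 13 of 16 members at 0 CDS reads in all libraries and was not tested as a list. These identifiers may be those of the uORFs themselves or wrong, so 0 reads does not mean that the intended genes lacked expression. The genes named for each light response were the 6 largest rises and the 6 largest falls among called genes with the same sign in both repeats and at least median abundance. From each list the 2 members with the smallest adjusted p were named, or the most abundant member where a list had no call. Within a condition the 3 highest and 3 lowest genes were named, and HY5, PHYA, COP1, PORA, PORB, HEMA1, CHS, ELIP1, LHCB1.3, RBCS1A, CCA1 and PIF3 in every comparison. Symbols, descriptions and neighbouring genes came from a reference annotation of the TAIR10.1 assembly, in which 26718 identifiers were matched. Its coordinates served only to find which loci overlap or neighbour each other, and none is printed.

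The repeat number was checked as a pairing. The deviations of same-numbered libraries from their group means correlated at 0.806 (mRNA dark and light), 0.735 (both kinds in the dark), 0.583 (mRNA dark and ribosome-protected light), 0.612 (mRNA light and ribosome-protected dark), 0.694 (both kinds after light) and 0.575 (ribosome-protected dark and light). With 2 repeats the deviations of a group mirror each other, and each value is across genes. The numbers were taken to pair the samples, and values from a fit with the repeat as a block are given beside a printed call or count where they change the call or move the count by over 1.5 times. The test without the block remained the principal one because it had been fixed in advance. Libraries of 1 group differed far beyond sampling noise, with a chi-square per gene between 62.5 and 294, so none was counted as a duplicate.

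The depth was 30997341 to 37245819 CDS reads in mRNA libraries and 4617343 to 40972194 in ribosome-protected ones, which makes the ratios of repeat 1 less precise for genes of low abundance. Intervals for shares are 95% Wilson intervals and cover counting error only.

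The tests were tried on simulated counts at the depths of the real libraries, with 50 genes changed at each of the log2 folds 1, 2, 3 and 4 among 19823. All other genes had no light effect, since dark and light means were averaged within each kind of library. The repeat entered as 1 shift per gene common to both kinds of library, which is the form that the block fits. Real repeat differences were not always common, with dark medians for plastid-encoded genes of log2 -2.96 in mRNA and -0.0030 in ribosome-protected reads. The recovery and false calls with the block therefore need not carry over to the real data. For the light effect on mRNA, edgeR without the block recovered 0, 10, 40 and 72% at these folds, and with the block 54, 96, 96 and 100% with 37 false calls. For ribosome-protected mRNA it was 0, 6, 30 and 54% without, and 38, 86, 94 and 100% with the block and 26 false calls. For translational efficiency DESeq2 without the block recovered 0, 24, 66 and 76% (2 false among 85 calls), and with the block 28, 78, 92 and 98% (28 false among 176 calls). In simulated data camera gave a p of 1.03e-19 for a raised set of 17 genes and passed the threshold in 4 of 100 random sets. Random sets lack the shared variation of genes in a real list. The check therefore cannot tell whether the preset inter-gene correlation suits the lists.

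The other settings chosen in advance were the repeat as a block, size factors of DESeq2 (1.42.0) in place of TMM, no filter, a filter of at least 50 reads in every group mean, the Wald test of DESeq2, limma-voom, the libraries of a comparison alone, organelle genes left out before scaling, a minimum log2 change of 1, an estimated correlation, and the omission of each library in turn. Alternatives on pseudocounts did not apply to counts. After the results had been seen, a block for each kind of library, the stricter filter with the block and DESeq2 with the block were added. With 2 libraries per group, other splits of the samples and tests for single deviating libraries were not made. The median log2 difference of all genes furthest from 0 was -0.0641 with TMM and -0.0820 with the size factors.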

Results

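Arabidopsis thaliana seedlings of the Col-0 accession were grown in darkness for 4 days, which gives the pale, elongated etiolated form with a closed apical hook. They were collected in the dark or after 4 h of white light, the stimulus that starts greening and opening of the seedling. From both conditions, steady-state mRNA and ribosome-protected mRNA were sequenced, the latter being the fragments that ribosomes shield when a polysome extract is digested with RNase I. This gave 4 groups of 2 libraries, numbered repeat 1 and repeat 2. The comparisons ask which mRNAs change in level with light, which change in ribosome-protected reads, and whether the ratio between both kinds of read, the translational efficiency, changes as well.

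The mRNA libraries held 30997341 to 37245819 reads in coding sequences (CDS). The ribosome-protected libraries were less even, with 4843438 in the dark and 4617343 after light in repeat 1, against 14974871 and 40972194 in repeat 2. Coding sequence took 95.8 to 98.3% of the ribosome-protected reads and 79.4 to 81.2% of the mRNA reads, and 3′ untranslated regions took 0.247 to 1.63% against 13.9 to 15.0%. Plastid-encoded genes took 2.59% (dark) and 4.54% (light) of the CDS reads of the mRNA libraries in repeat 1, but 0.253% and 0.369% in repeat 2. Their share of the ribosome-protected reads was 0.652% and 2.50% in repeat 1, and 1.23% and 2.88% in repeat 2. The 95% Wilson intervals of these shares were at most 0.0142 percentage points to either side, for counting error only. In a principal component analysis of 19823 genes, component 1 (42.7% of the variance) placed dark libraries at -106.6 to -39.9 and light libraries at 32.6 to 110.7. Component 2 (26.7%) separated mRNA from ribosome-protected libraries, and component 3 (20.6%) separated repeat 1 (28.5 to 78.9) from repeat 2 (-78.2 to -21). The labels do not say whether the repeats were separate cultures, so p-values measure only the spread between these samples.

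In edgeR over all genes, light raised the steady-state mRNA of 16 of 20 light-harvesting genes and of 24 of 30 genes for photosystem and electron transport subunits, and lowered that of 11 of 19 auxin response genes. LHCB1.4 (AT2G34430), a chlorophyll-binding protein of the photosystem II antenna, rose from 1.63 and 4.40 CPM (read counts scaled to library size) in the dark to 313 and 623 CPM after light, a log2 fold change of 7.27 ± 0.79 (SE, n = 2 libraries per group; adjusted p = 0.00862). SNRK2.5 (AT5G63650), a protein kinase of the SnRK2 family, fell from 88.5 and 214 CPM to 3.81 and 3.41 CPM (log2 -5.39 ± 0.76, adjusted p = 0.0163). HY5 (AT5G11260), the bZIP factor that promotes photomorphogenesis, rose by 1.70 ± 0.23 (adjusted p = 0.0150), and COP1 (AT2G32950), the ubiquitin ligase that represses it in the dark, rose by 1.03 ± 0.20 (adjusted p = 0.0407). Across all genes 662 rose and 285 fell in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and all 947 moved the same way in both repeats. The calls rest on both repeats, so this shared direction is not independent support.

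Among called genes of at least median abundance, the largest rises besides LHCB1.4 were those of LHCB1.1 (7.24 ± 0.68), LHCB1.2 (6.58 ± 1.01) and MSRB6 (6.38 ± 0.41), a methionine sulfoxide reductase. LHCB2.2 (6.29 ± 0.49) and CDSP32 (6.02 ± 0.39), a plastid thioredoxin-like protein, followed. Adjusted p lay between 0.00466 and 0.0209 for the 5. The LHCB1 and LHCB2 genes are near-identical copies, so the division of their reads between copies is uncertain. The largest falls of such called genes besides SNRK2.5 were those of AT4G11610, a C2-domain protein (-5.35 ± 0.61), and AT2G34020, an EF-hand protein (-5.20 ± 0.87). GH9B13, a glycosyl hydrolase (-4.81 ± 0.37), followed. GH3.3, an auxin-conjugating enzyme (-4.25 ± 0.73), and AT1G77330, a member of the 2-oxoglutarate and iron-dependent oxygenase superfamily (-4.25 ± 0.48), came next, and adjusted p ran from 0.00590 to 0.0291.

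All 20 light-harvesting genes had higher mRNA after light, and 16 passed over all genes tested (20 adjusted over the list alone). Their median log2 change was 3.86 (4.32 in repeat 1, 3.95 in repeat 2). Camera, which compares a list with all other genes at a preset inter-gene correlation, gave these genes an adjusted p of 5.13e-26 (adjusted p = 0.191 with an estimated correlation). Of 30 nuclear genes for photosystem and electron transport subunits, 24 rose (30 adjusted over the list alone), with a median of 3.01 and examples in PSBO2 (4.39 ± 0.38) and PSAL (2.98 ± 0.32). Their camera value was 2.27e-28 (adjusted p = 0.242 with an estimated correlation). Of 24 genes for chlorophyll synthesis, 6 rose, namely CAO, HEMA1, CRD1, GUN4, CHLM and CHLH (13 up and 1 down adjusted over the list alone, 22 up and 1 down over all genes with the block). HEMA1, the glutamyl-tRNA reductase, rose by 2.35 ± 0.32 and GUN4, a regulator of magnesium chelatase, by 3.56 ± 0.49. The list median was 1.71 (camera 7.25e-09, adjusted p = 0.441 with an estimated correlation). Of 18 Calvin cycle genes, GAPA2 (3.54 ± 0.47), CP12-2 (4.02 ± 0.39), RCA and RPE rose (14 adjusted over the list alone, 17 over all genes with the block), with a median of 2.72 (camera 1.77e-10, adjusted p = 0.260 with an estimated correlation). Of 31 nuclear genes for plastid ribosomal proteins, 0 passed in edgeR without a block, over all genes or adjusted over the list alone (5 at an unadjusted p under the threshold; DESeq2 called 2). All 31 were higher after light. Their median was 1.27 (1.76 and 1.06 in the repeats; camera 2.26e-06, adjusted p = 0.585 with an estimated correlation). With the repeat as a block 29 passed. The dark mRNA libraries differed between repeats for several of these lists, with repeat 2 above repeat 1 by a median log2 of 1.73 in the Calvin cycle, 1.37 in plastid ribosomal proteins, 0.82 in chlorophyll synthesis, 0.52 in photosystem subunits and 0.39 in light-harvesting genes.

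Of 19 Aux/IAA and SAUR genes, the early targets of auxin, 11 fell (16 adjusted over the list alone, 17 over all genes with the block), with a median of -1.82 (-1.91 and -1.80 in the repeats). IAA19 fell by 2.80 ± 0.29 and SAUR19, which has near-identical neighbours, by 2.84 ± 0.37. Camera gave 5.11e-15, and this list alone stayed under the threshold with an estimated correlation (adjusted p = 0.0372; 0.0581 with the block as well). Of 11 genes for ethylene and the apical hook, ACS5 (-5.65 ± 0.65) and ACS8 (-5.48 ± 0.91), enzymes of ethylene precursor synthesis, fell (5 adjusted over the list alone, 8 over all genes with the block). Camera gave 4.81e-05 for the list (adjusted p = 0.242 with an estimated correlation). EXPA11 (-3.41 ± 0.52), XTH15 (-3.56 ± 0.36) and XTH19 fell among 17 expansins and xyloglucan endotransglucosylases, which loosen the cell wall (7 down and 2 up adjusted over the list alone, 10 down and 4 up over all genes with the block). For these genes camera gave 0.00767 (adjusted p = 0.260 with an estimated correlation; 0.0543 with a separate block for each kind of library, added after the results were seen). RGL1, a DELLA repressor, fell by 1.12 ± 0.20 as the only call without the block among 14 gibberellin and brassinosteroid genes (4 down and 2 up adjusted over the list alone, 7 down and 2 up over all genes with the block). The camera value was 0.0394 (adjusted p = 0.585 with an estimated correlation). PIN2, a root auxin transporter, fell by 1.92 ± 0.32 as the only one of 7 tested root markers without the block, over all genes and adjusted over the list alone (3 down over all genes with the block; camera 0.0293, adjusted p = 0.257 with an estimated correlation).

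Regulators of the light response moved in both directions. Of 26 light signalling factors, SPA4, BBX22, BBX25 (5.40 ± 0.51), COP1, SPA3, HYH and HY5 rose, and ATHB2 (-2.99 ± 0.26), a shade-induced homeodomain factor, and FHL, a nuclear import factor of phytochrome A, fell (11 up and 5 down adjusted over the list alone, 14 up and 5 down over all genes with the block). Camera gave 0.0147 for the list (adjusted p = 0.441 with an estimated correlation). Of 10 photoreceptor genes 0 passed in edgeR over all genes (5 unadjusted; DESeq2 called 4) and 2 up and 1 down adjusted over the list alone, against 3 up and 2 down over all genes with the block. PHYA (AT1G09570), the far-red phytochrome of dark-grown seedlings, was fitted at -1.66 ± 0.44 (adjusted p = 0.0950; 5.29e-04 with the block). UGT78D2, a flavonoid glucosyltransferase, rose by 4.38 ± 0.76 as the only call without the block among 15 flavonoid genes (5 adjusted over the list alone, 14 over all genes with the block), whose median was 4.37 (3.01 and 4.26 in the repeats; camera 5.48e-05, adjusted p = 0.566 with an estimated correlation). In the dark these genes were a median log2 of 1.85 higher in repeat 2. ELF4 rose by 2.43 ± 0.34 as the only one of 16 clock genes without the block, adjusted over the list alone as well (8 up and 1 down with the block; camera 0.219). HSP70-4 (3.0 ± 0.33) and HSP101 (1.05 ± 0.21) rose among 9 heat shock and oxidative stress genes (3 adjusted over the list alone, 6 over all genes with the block; camera 0.00752, adjusted p = 0.242 with an estimated correlation). VTC2 (2.03 ± 0.28) rose among 3 tested genes with a conserved peptide uORF (2 adjusted over the list alone and 2 over all genes with the block). Of the 16 listed, 13 were at 0 CDS reads in all libraries, which may stem from the listed identifiers, so the list had no camera test. Also up were TCP3 (1.48 ± 0.30) and TCP10 (1.95 ± 0.27) among 34 miRNA targets, both also adjusted over the list alone (7 up and 5 down over all genes with the block). PCK1, which turns stored lipid carbon toward sugar, fell by 2.86 ± 0.41 among 10 seed reserve genes (1 up and 1 down adjusted over the list alone, 1 up and 4 down over all genes with the block; camera 0.143).

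In edgeR over all genes, several well-known light genes passed with the repeat as a block and not without it. CHS was fitted at 4.37 ± 2.14 (adjusted p = 0.343; 1.34e-04 with the block), ELIP1 at 6.44 ± 1.77 (0.106; 5.92e-05), PORA at -5.67 ± 1.41 (0.0815; 4.12e-04), and LHCB1.3 at 2.87 ± 1.02 (0.192; 0.00148). The same held for RBCS1A, one of several near-identical small subunit genes, at 1.95 ± 1.03 (0.386; 0.0103) and CCA1 at 1.08 ± 0.40 (0.213; 0.00712). Without the block, ELIP1, PORA and LHCB1.3 also passed adjusted over their list alone and in DESeq2, as did PHYA. PORB (-0.98 ± 1.07; 0.33 in repeat 1 and -1.41 in repeat 2) and PIF3 (-0.07 ± 0.30) passed neither way. The count of calls in edgeR was 0 among 192 cytosolic ribosomal protein genes (median 0.01; 6 up and 3 down with the block), 28 translation factors (median -0.05; 1 up and 2 down with the block), 12 cell cycle genes (median 0.22; 1 with the block), and 8 stomatal lineage genes (median 1.36; 5 up and 1 down with the block). It was 0 among 80 plastid-encoded genes (median 0.55; 3 with the block) and 46 mitochondrion-encoded genes (median -0.04; 0 with the block) too, and 0 in all 6 lists adjusted over the list alone. At an unadjusted p, 6 members of these 6 lists were under the threshold, and DESeq2 called 1 stomatal and 1 plastid-encoded gene. For none of these lists was the camera call past the threshold (adjusted p from 0.113 to 0.902), although plastid-encoded genes passed with a separate block for each kind of library (6.23e-05). The camera sign was down for the cytosolic ribosomal proteins although their median was just above 0, and up for the miRNA targets although theirs was -0.04.

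The count of mRNA calls depended on how the repeats were treated. With the repeat as a block it was 6659 (3838 up, 2821 down), which included all 947, and the estimated biological coefficient of variation was 0.391 without and 0.170 with the block. In simulated counts the fit with the block made more false calls than the threshold allows. The count was 2234 with DESeq2 without a block and 0 with edgeR on the 4 mRNA libraries alone, where 3224 genes had an unadjusted p under the threshold. Leaving out the dark mRNA library of repeat 1 left 3 calls, that of repeat 2 left 32, the light mRNA library of repeat 1 173, that of repeat 2 98, and either light ribosome-protected library 457. The camera call on light signalling was lost without the dark mRNA library of repeat 2 (adjusted p = 0.0511). The call on root markers was lost without the same library (0.0718) or the light mRNA library of repeat 1 (0.0708). That on gibberellin and brassinosteroid was lost without either dark ribosome-protected library (0.0541 and 0.0542), the dark mRNA library of repeat 1 (0.250) or the light mRNA library of repeat 2 (0.0850). Calls were gained for plastid-encoded genes without the dark mRNA library of repeat 1 (1.70e-10) or the light one of repeat 2 (1.59e-12). They were gained with the opposite sign without the dark one of repeat 2 (0.0123) or the light one of repeat 1 (0.00364). For cytosolic ribosomal proteins they were gained without the dark mRNA library of repeat 1 (4.99e-04), the light one of repeat 2 (0.00154) or, with the opposite sign, the dark one of repeat 2 (0.0332). Clock genes gained one without the dark mRNA library of repeat 1 (0.00803), mitochondrion-encoded genes without that of repeat 2 (0.0358), and seed reserves without the light mRNA library of repeat 1 (0.0425). Stomatal lineage genes gained one without either dark ribosome-protected library (0.0428 and 0.0430), the dark mRNA library of repeat 2 (0.0329) or the light one of repeat 1 (0.0414). Whether reads were counted by strand is not given in the sources used here, so reads of overlapping and antisense genes cannot be separated.

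**Figure D1:**
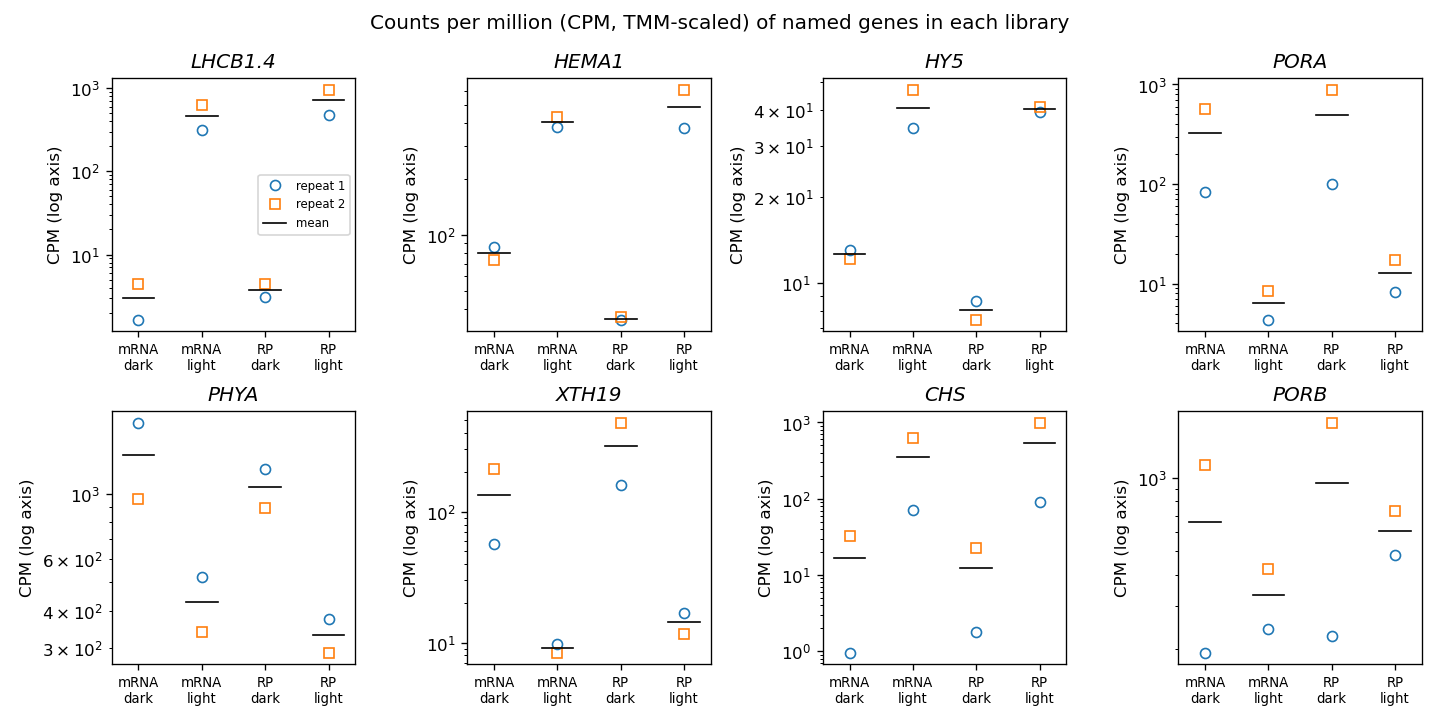
CPM, read counts scaled to library size (log axis), of 8 genes in each library, grouped as mRNA dark, mRNA light, ribosome-protected dark and ribosome-protected light, with both repeats as points and the group mean as a bar. LHCB1.4, HEMA1 and HY5 lie higher after light in both repeats and both kinds of library, XTH19 lies lower, and PORB changes sign between repeats.

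Ribosome-protected reads rose in 19 of 20 light-harvesting and 9 of 24 chlorophyll synthesis genes and fell in 13 of 19 auxin response genes in edgeR over all genes. LHCB1.4 rose by 7.55 ± 0.81 on the log2 scale (adjusted p = 0.00595), from 3.12 and 4.43 CPM to 481 and 958 CPM, and LHCA1 (AT3G54890), of the photosystem I antenna, by 6.39 ± 0.44 (adjusted p = 0.00430). HEMA1 (AT1G58290) rose by 3.79 ± 0.35 and HY5 by 2.33 ± 0.24, while SNRK2.5 fell by 5.91 ± 0.80 and XTH19 by 4.49 ± 0.82 (adjusted p from 0.00430 to 0.0269). In total 934 genes rose and 421 fell, all of them in the same direction in both repeats, on which the calls themselves rest. Both tests called 847 genes, 604 up and 243 down, against 31.2 and 6.05 for independent lists of these sizes. With the repeat as a block they shared 4912, of which 2889 were up and 2014 down in both, against 665 and 413. The libraries of both tests are paired by repeat (deviations correlated at 0.735 in the dark and 0.694 after light) and share an estimate of spread, so the lists are not independent.

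The largest rises among called genes of at least median abundance were completed by LHCB1.2 (7.49 ± 1.06), LHCB1.1 (7.46 ± 0.69), MSRB6 (6.78 ± 0.42) and LHCB3 (6.48 ± 0.51). The largest falls of such called genes were completed by GH9B13 (-4.92 ± 0.38), AT4G11610 (-4.92 ± 0.61), AT2G34020 (-4.84 ± 0.88) and AT1G77330 (-4.49 ± 0.48). Of the light-harvesting genes 19 of 20 rose (20 adjusted over the list alone), now including LHCB1.3 (5.18 ± 1.14, adjusted p = 0.0462). They had a median of 5.21 (5.12 and 5.07 in the repeats). For these genes camera gave 2.46e-24 (adjusted p = 0.203 with an estimated correlation). Photosystem subunits rose in 26 of 30 (30 adjusted over the list alone), with a median of 3.30 and PSBO2 (4.49 ± 0.38) and PSAN (3.57 ± 0.38) among them (camera 1.28e-25, adjusted p = 0.203 with an estimated correlation). In chlorophyll synthesis 9 of 24 rose (14 up and 1 down adjusted over the list alone, 22 up and 1 down over all genes with the block), CHLM by 3.19 ± 0.30, with a median of 2.26 (camera 2.35e-10, adjusted p = 0.408 with an estimated correlation). In the Calvin cycle 9 of 18 rose (17 adjusted over the list alone, 18 over all genes with the block), CP12-2 by 4.42 ± 0.40 and GAPA2 by 4.18 ± 0.48, with a median of 3.73 (camera 1.36e-12, adjusted p = 0.203 with an estimated correlation). Plastid ribosomal proteins had 0 calls in edgeR, also adjusted over the list alone (17 unadjusted; DESeq2 called 7). All 31 members were higher after light, with a median of 1.60 (2.40 and 1.36; camera 6.51e-09, adjusted p = 0.490 with an estimated correlation) and 31 calls with the block.

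Auxin response genes fell in 13 of 19 (18 adjusted over the list alone), with IAA19 at -3.20 ± 0.30, SAUR19 at -3.37 ± 0.39 and a list median of -2.59 (-2.57 and -2.53 in the repeats). Camera gave 1.32e-15, again the only list under the threshold with an estimated correlation (adjusted p = 0.0345; 0.0550 with the block as well). EXPA11 (-3.91 ± 0.53), XTH15 (-3.40 ± 0.36), EXPA8, XTH5 and XTH19 fell among the wall-loosening genes (7 down and 2 up adjusted over the list alone, 11 down and 4 up over all genes with the block; camera 0.00265, adjusted p = 0.203 with an estimated correlation). ACS5 (-6.30 ± 0.72) and ACS8 (-5.66 ± 1.00) fell among ethylene and hook genes (4 adjusted over the list alone, 8 over all genes with the block). The camera value was 1.49e-04 (adjusted p = 0.203 with an estimated correlation). RGL1 (-1.29 ± 0.20) was the only call in its list without the block (4 down and 1 up adjusted over the list alone, 9 down and 1 up over all genes with the block; camera 0.0113, adjusted p = 0.490 with an estimated correlation). So was PIN2 (-2.22 ± 0.33) in the root markers, also adjusted over the list alone (4 down over all genes with the block; camera 0.00707, adjusted p = 0.203 with an estimated correlation).

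PHOT2, the blue-light receptor phototropin 2, rose by 2.77 ± 0.50 and PHYE by 1.01 ± 0.20 (2 up and 1 down adjusted over the list alone, 3 up and 2 down over all genes with the block; camera for photoreceptors 0.556). Of the light signalling factors 6 rose, BBX22, BBX25 (5.81 ± 0.55), COP1 (1.07 ± 0.20), SPA3, HYH and HY5, and FHY1, FHL and ATHB2 (-3.31 ± 0.27) fell (12 up and 5 down adjusted over the list alone, 13 up and 5 down over all genes with the block). Camera gave 0.0190 for the list (adjusted p = 0.459 with an estimated correlation). UGT78D2 (4.47 ± 0.78) was the only flavonoid call without the block, also adjusted over the list alone, against 14 of 15 with the block (camera 1.65e-04, adjusted p = 0.500 with an estimated correlation). ELF4 (2.44 ± 0.35) was the only clock call without the block, also adjusted over the list alone (7 with the block; camera 0.108, and 0.0414 with the block, where adjusted p = 0.627 with an estimated correlation). HSP70-4 (3.04 ± 0.33) and HSP101 (1.33 ± 0.21) rose (3 adjusted over the list alone, 4 up and 1 down over all genes with the block; camera 0.010, adjusted p = 0.203 with an estimated correlation). Also up were VTC2 (1.84 ± 0.28), TCP10 (2.78 ± 0.30) and TCP3 (1.87 ± 0.33), each also adjusted over the list alone, while with the block 2 uORF genes passed upward and 6 miRNA targets upward and 4 downward. CAT2, a catalase of peroxisomes, rose by 2.05 ± 0.35 and PCK1 fell by 1.86 ± 0.40 among seed reserve genes, the same counts as adjusted over the list alone (1 up and 3 down over all genes with the block; camera 0.517).

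Of 80 plastid-encoded genes 3 rose, the same number adjusted over the list alone and 15 with the block, with psbA (ATCG00020) at 2.82 ± 0.44 and petB (ATCG00720) at 2.80 ± 0.53. The list median was 1.15 (0.79 and 1.35). For these genes camera gave 4.92e-04 (adjusted p = 0.712 with an estimated correlation). The 46 mitochondrion-encoded genes had 0 calls in edgeR, also adjusted over the list alone (4 unadjusted, 2 down in DESeq2, 4 down with the block). Their median was -0.86 (-1.53 and -0.55; camera 4.92e-04, adjusted p = 0.459 with an estimated correlation), or -0.71 over 43 members once groups without a read were set to 3 reads over the group. Stomatal lineage genes had 0 calls in edgeR, also adjusted over the list alone (3 unadjusted, 2 in DESeq2, 5 with the block), and a median of 1.56 (camera 0.0290, adjusted p = 0.608 with an estimated correlation). Cytosolic ribosomal proteins (median 0.06; 5 up and 2 down with the block), translation factors (median 0.08; 1 with the block) and cell cycle genes (median -0.07, mean 0.03; 1 up and 1 down with the block) had 0 calls in edgeR over all genes and adjusted over the list alone (2, 0 and 3 unadjusted; 0 in DESeq2). Their camera p-values, like that of the miRNA targets (0.881, sign up with a median of -0.15), were above the threshold. PHYA (-1.67 ± 0.44, adjusted p = 0.0770), PORA (-5.24 ± 1.39, 0.0785), CHS (5.42 ± 2.26, 0.231), ELIP1 (6.13 ± 1.75, 0.0978), RBCS1A (2.75 ± 1.06, 0.198) and CCA1 (1.11 ± 0.42, 0.188) passed in edgeR over all genes with the block and not without it. Without the block, adjusted over the list alone, PHYA, PORA, ELIP1 and RBCS1A passed, and DESeq2 called these and CHS. PORB (-0.64 ± 1.07; 1.1 in repeat 1, -1.20 in repeat 2) and PIF3 (-0.08 ± 0.31) passed in neither fit.

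With the repeat as a block 6341 genes passed (3437 up, 2904 down), including all 1355, and DESeq2 without a block called 2690. edgeR on the 4 ribosome-protected libraries alone called 634. The count was 176 without the light ribosome-protected library of repeat 2, 430 without that of repeat 1, 232 and 231 without the dark ribosome-protected libraries of repeat 1 and repeat 2, and 846 and 820 without the light mRNA libraries of repeat 1 and repeat 2. The camera call on light signalling was lost without the dark ribosome-protected library of repeat 2 (adjusted p = 0.152) or the light one of repeat 1 (0.0720). Those on gibberellin and brassinosteroid (0.0897 and 0.0621) and on stomatal lineage genes (0.111 and 0.162) were lost without the dark ribosome-protected library of repeat 1 or the light one of repeat 2. Cytosolic ribosomal proteins gained a call without the dark ribosome-protected library of repeat 2 (3.37e-04) or the light one of repeat 1 (2.26e-04). The call came with the opposite sign without the dark one of repeat 1 (4.57e-04) or the light one of repeat 2 (0.00350). Clock genes gained one without the dark one of repeat 1 (0.00156) or the light one of repeat 2 (0.0413), and cell cycle genes without the latter (0.0496).

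**Figure D2:**
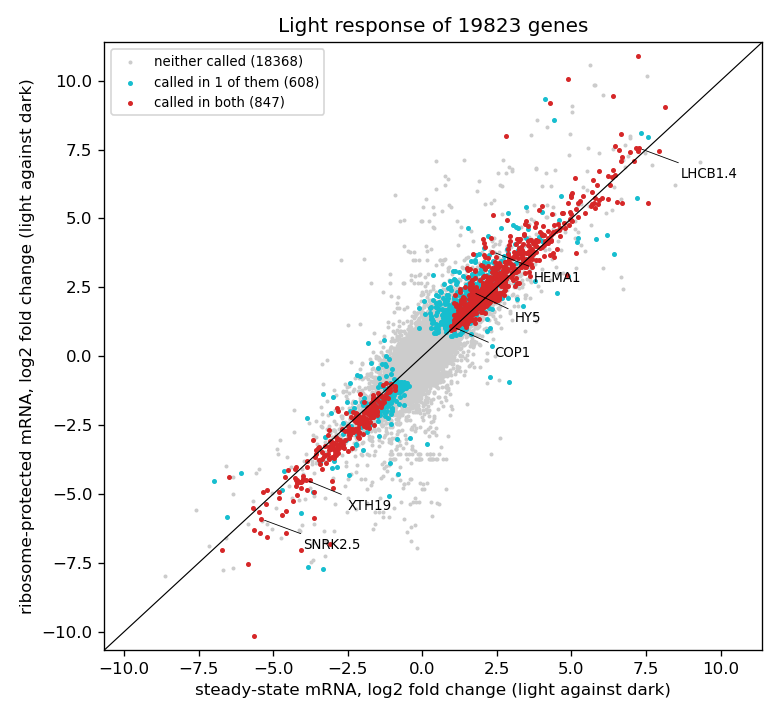
Light response of 19823 genes as log2 fold change of ribosome-protected mRNA (vertical axis) against that of steady-state mRNA (horizontal axis), coloured by whether a gene passed in both comparisons (847), in 1 of them (608) or in neither (18368), with the line of equality. Named genes such as LHCB1.4 and HEMA1 lie at the upper right and SNRK2.5 and XTH19 at the lower left.

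Translational efficiency was compared through the interaction of light with the kind of library, which asks whether ribosome-protected reads changed more than mRNA, relative to the average gene. Scaling by TMM places the average gene near no change, so a change in translation shared by most genes would not be seen. No single gene passed in edgeR over all genes, and camera placed photosynthesis lists above and auxin response below all other genes. With an estimated correlation 0 of the list calls held (adjusted p = 0.207 for auxin response and 0.699 to 0.783 for the others). Fry, which tests a list against no change, called 0 lists without the block (adjusted p = 0.264 for auxin response and 0.991 for the others with a camera call). With the block it called 1, auxin response (adjusted p = 0.0295). LHCB4.2 (1.88 ± 0.47; 2.04 in repeat 1 and 1.67 in repeat 2), an antenna protein, and PRK (1.88 ± 0.74), the phosphoribulokinase of the Calvin cycle, were fitted above 0. CHLM (1.69 ± 0.39), CP12-1 (1.68 ± 0.47), HEMA1 (1.44 ± 0.44; 1.28 and 1.51), CHLH (1.42 ± 0.69) and LHCA4 (1.42 ± 0.48) were also fitted above 0, with an adjusted p of 1 for each and of 0.150 (CHLM) to 0.365 (CHLH) with the block. HY5 was fitted at 0.63 ± 0.33, COP1 at 0.03 ± 0.28 and PHYA at -0.01 ± 0.61.

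All 18 Calvin cycle genes were fitted above 0, with a median of 0.72 (0.96 in repeat 1, 0.76 in repeat 2). The camera value was 1.79e-06 (adjusted p = 0.699 with an estimated correlation). For light-harvesting genes it was 18 of 20 with a median of 0.62 (0.54 and 0.85; camera 1.34e-07, adjusted p = 0.699 with an estimated correlation), and for chlorophyll synthesis 20 of 24 with 0.37 (0.52 and 0.36). Camera gave 3.27e-05 for the list (adjusted p = 0.783 with an estimated correlation). Plastid ribosomal proteins (27 of 31 above 0) had a median of 0.32 (0.66 and 0.19; camera 0.00216, adjusted p = 0.783 with an estimated correlation) and photosystem subunits (21 of 30) one of 0.17 (0.37 and 0.11). For these genes camera gave 0.00429 (adjusted p = 0.783 with an estimated correlation). All 19 auxin response genes were fitted below 0, with a median of -0.44 (-0.44 and -0.45; camera 2.46e-06, adjusted p = 0.207 with an estimated correlation), IAA5 at -0.82 ± 0.45 and SAUR15 at -0.70 ± 0.46. Plastid-encoded genes had a median of 0.35 (0.18 and 1.00; 51 of 80 above 0). The camera value was 5.59e-05 (adjusted p = 0.783 with an estimated correlation). Mitochondrion-encoded genes had a median of -0.73 (-1.10 and -0.83; camera 8.09e-07, adjusted p = 0.699 with an estimated correlation), or -0.69 over 42 members with groups at 0 set to 3 reads. Not one camera call held with an estimated correlation.

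The other 15 lists had no camera call, although cytosolic ribosomal proteins (0.0395) and translation factors (0.0418) passed with a separate block for each kind of library. Their medians included 0.10 for flavonoid genes, -0.09 for light signalling, 0.05 for the clock, 0.07 for cytosolic ribosomal proteins, 0.05 for translation factors, -0.37 for wall-loosening genes, -0.25 for gibberellin and brassinosteroid, -0.24 for ethylene and hook genes, -0.19 for the cell cycle, -0.27 for root markers, 0.18 for stomatal lineage genes, 0.03 for photoreceptors and -0.03 for miRNA targets. For heat shock genes (median -0.10) the camera sign was up, and for seed reserves the median was -0.01 with a mean of 0.28. In edgeR 0 members of the 24 lists passed over all genes, with or without the block, and 0 adjusted over the list alone without it. With the block and adjusted over the list alone, LHCB4.2, LHCB3, LHCA4, LHCB4.1 and LHCA3 rose in the light-harvesting list and CHLM, CHLP, HEMA1, CHLH and FLU in chlorophyll synthesis. So did GAPA1, CP12-1, RPE and PRK in the Calvin cycle and ICL in seed reserves, while XTH5 fell among wall-loosening genes. Those of the 16 outside the rule for named genes were chosen after their values were seen. Of 680 members 13 were under the threshold unadjusted, and DESeq2 without the block called 2, 1 each in the light-harvesting and chlorophyll synthesis lists.

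Without the block edgeR called 0 of 19823 genes, with 261 at an unadjusted p under the threshold against 991 from chance alone, and with the block 0, with 1233 unadjusted. DESeq2 called 15 (13 up, 2 down), or 204 (199 up, 5 down) with the block in a fit added after the results were seen, and limma-voom 0 (213 unadjusted). In simulated data with added efficiency changes, edgeR without the block recovered 0% even at a log2 change of 4. With the block it recovered 24% at 1, 82% at 2, 92% at 3 and 100% at 4. In that setting edgeR without the block thus did not detect single-gene changes of these sizes. The simulated repeat effect had the form that the block fits, so the recovery with the block need not hold for the real data. The simulated calls with the block included 25 false ones. Across genes, the efficiency change in repeat 1 and repeat 2 correlated at r = 0.260 over all 19823 genes and 0.670 over 5578 abundant ones, where genes are not independent replicates. Omitting single libraries left 0 calls on genes in edgeR in each case (144 to 449 unadjusted) and moved camera calls on lists. Without the dark ribosome-protected library of repeat 1 the calls on Calvin cycle (0.0872), chlorophyll synthesis (0.410), photosystem (0.527, sign turned) and plastid ribosomal proteins (0.114, sign turned) were lost. Without the dark mRNA library of repeat 2 those on the same lists (0.0870, 0.386, 0.582 and 0.778, the last with its sign turned) and on mitochondrion-encoded genes (0.0750) were lost. Without the light mRNA library of repeat 1, chlorophyll synthesis (0.0872), photosystem (0.304) and plastid ribosomal proteins (0.397) were lost, and without the light ribosome-protected library of repeat 2 the latter pair (0.443 and 0.276). The sign for plastid-encoded genes turned without the dark mRNA library of repeat 1 (0.0201) or the light mRNA library of repeat 2 (0.0102). The number of lists called was 13 without the light ribosome-protected library of repeat 1, against 8 with all libraries. Every single omission gave cytosolic ribosomal proteins a call, from 8.15e-10 without the light ribosome-protected library of repeat 1 to 0.0275 without the light mRNA library of repeat 1, the sign being opposite to the fit over all libraries in 4 of the 8 cases. Other lists gained calls without single libraries, among them flavonoid genes (0.00435 without the light ribosome-protected library of repeat 1, and 0.0189 with the opposite sign without the light mRNA library of repeat 1), the clock (5.45e-04 without the dark ribosome-protected library of repeat 1), the cell cycle (3.58e-04 without the light mRNA library of repeat 1) and translation factors (0.00231 without the light ribosome-protected library of repeat 1).

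**Figure D3:**
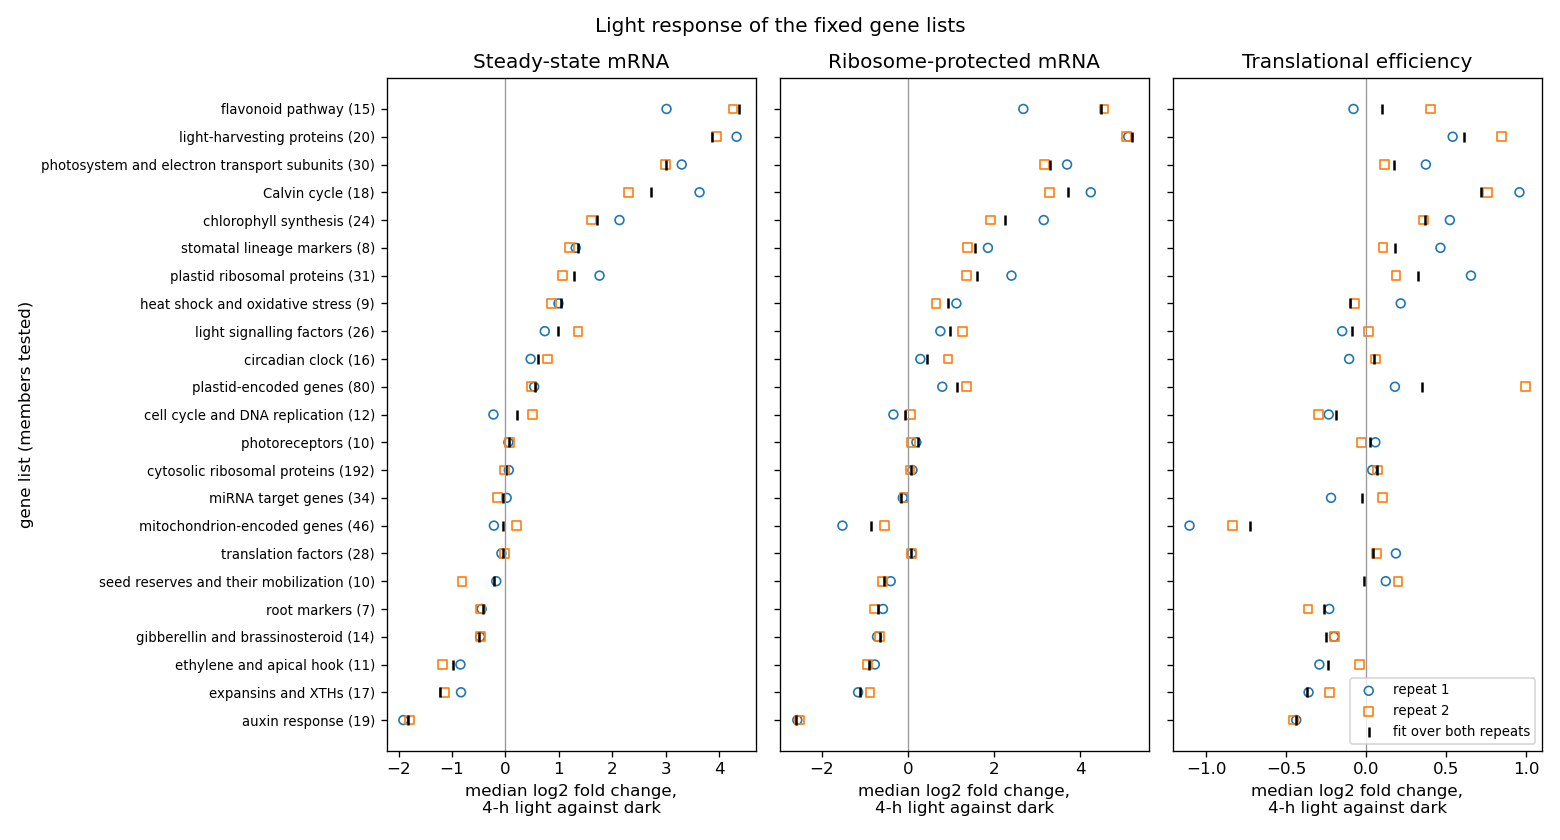
Median log2 light response of 23 gene lists in mRNA, ribosome-protected mRNA and translational efficiency, with circles for repeat 1, squares for repeat 2 and a bar for the fit over both. Light-harvesting genes lie at 3.86, 5.21 and 0.62 and auxin response genes at -1.82, -2.59 and -0.44 in the 3 measures.

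Within each condition, ribosome-protected reads were set against mRNA to find genes with many or few ribosome fragments for their mRNA, relative to the average gene. In the dark 9 of 34 miRNA target genes were lower in ribosome-protected reads and none higher (15 adjusted over the list alone, 18 over all genes with the block), among them PHV, PHB, TOE1, TCP3 and the HAIRY MERISTEM genes, with a list median of -1.04 (-0.96 and -1.0 in the repeats). DCL1 (AT1G01040), the nuclease that makes miRNAs and is itself a miRNA target, stood at -2.43 in the dark (adjusted p = 0.0266) and -1.67 after light (adjusted p = 0.0347). It was picked after its values were seen. Cytosolic ribosomal protein genes lay above 0 in 181 of 192 members, with a median of 0.62. AT5G21020 (-4.52 ± 0.50), AT4G34881 (-4.27 ± 0.66), both uncharacterized, and AT3G60300, an RWD-domain protein (-3.52 ± 0.49), were lowest, with adjusted p from 0.0266 to 0.0327.

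Highest in the dark were AT2G35750 (4.12 ± 0.78), whose locus overlaps snoRNA genes, mitochondrial cox1 (ATMG01360; 3.35 ± 0.66) and plastid psbH (ATCG00710; 3.21 ± 0.51), with adjusted p from 0.0332 to 0.0448. For organelle-encoded genes a high ratio can come from few reads kept in the mRNA libraries as well as from many ribosome fragments. The plastid share of mRNA reads in the dark was 2.59% in repeat 1 and 0.253% in repeat 2. Camera gave 5.79e-08 for miRNA targets (adjusted p = 0.132 with an estimated correlation) and 5.79e-08 for cytosolic ribosomal proteins (adjusted p = 0.864 with an estimated correlation). The latter had 0 member calls in edgeR over all genes and adjusted over the list alone (26 unadjusted; 10 up and 1 down in DESeq2) and 116 up and 2 down with the block. Auxin response genes had a median of 0.80 with 19 of 19 above 0 (camera 1.45e-06, adjusted p = 0.132 with an estimated correlation), with 0 member calls in edgeR and adjusted over the list alone, 10 unadjusted, 3 in DESeq2 and 14 with the block. Wall-loosening genes had 0.91, where EXPA6 passed (3 adjusted over the list alone, 11 up and 1 down with the block; camera 1.93e-04, adjusted p = 0.212 with an estimated correlation), and photosystem subunits had 0.72 (camera 5.88e-04, adjusted p = 0.864 with an estimated correlation). CASP1 and CASP2, of the endodermal barrier, passed among root markers (5 with the block; camera 0.00910, adjusted p = 0.212 with an estimated correlation). Clock genes were lower (median -0.76; PRR3 passed, 3 adjusted over the list alone, 10 down and 1 up over all genes with the block; camera 0.0268, adjusted p = 0.864 with an estimated correlation), as were photoreceptors (median -0.46; PHYE passed, 4 with the block). Camera gave 0.0470 for the list (adjusted p = 0.316 with an estimated correlation). Plastid-encoded genes had a median of -0.83, made of -1.81 in repeat 1 and 2.1 in repeat 2, while camera gave the opposite sign (0.0261, adjusted p = 0.962 with an estimated correlation; 0.230 with the block). The call on translation factors (0.0424, adjusted p = 0.864 with an estimated correlation) was also lost with the block (0.0507).

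After light, miRNA targets again lay lower, with 8 of 34 passed (17 adjusted over the list alone, 22 over all genes with the block), a median of -0.84 and camera at 3.56e-09 (adjusted p = 0.205 with an estimated correlation). Cytosolic ribosomal proteins lay higher, with 191 of 192 above 0, a median of 0.73 and camera at 4.70e-12 (adjusted p = 0.568 with an estimated correlation; 0 member calls in edgeR and adjusted over the list alone, 18 unadjusted, 6 in DESeq2, and 122 up and 1 down with the block). Photosystem subunits had all 30 members above 0 (median 0.87; camera 1.05e-08), light-harvesting genes all 20 (0.66; 3.70e-05) and plastid ribosomal proteins all 31 (0.80; 3.40e-04), each with adjusted p = 0.568 with an estimated correlation. AT4G34881 (-4.94 ± 0.71), AT5G21020 (-4.86 ± 0.52) and RAP2.4, an ERF-family factor (-4.14 ± 0.49), were lowest. Plastid psbT (ATCG00690; 3.55 ± 0.56), psbH (3.32 ± 0.51) and petD (ATCG00730; 2.91 ± 0.52) were highest, with adjusted p from 0.0282 to 0.0458. The limit given for organelle-encoded genes in the dark holds here too. After light the plastid share of mRNA reads was 4.54% in repeat 1 and 0.369% in repeat 2. Plastid-encoded genes as a list had a median of -0.03 (-1.14 in repeat 1, 3.23 in repeat 2), while camera put them up (6.67e-06, adjusted p = 0.568 with an estimated correlation). Photoreceptors had a camera call, downward, only with the block (0.0760 without, 0.0296 with it, and adjusted p = 0.310 with the block and an estimated correlation).

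In the dark 156 genes were higher and 767 lower in ribosome-protected reads, 923 in total (8004 with the block, 2696 with DESeq2). After light it was 20 and 467, 487 in total (6470 with the block, 1724 with DESeq2, 180 with at least 50 reads in every group mean). Omitting any 1 of the 8 libraries left 0 calls in the dark in edgeR (3108 to 4456 at an unadjusted p under the threshold). After light it left 262 or 276 without the dark ribosome-protected library of repeat 1 or repeat 2 and 0 without any other (2228 to 3355 unadjusted). edgeR on the 4 libraries of a condition alone also gave 0 (3641 in the dark and 3341 after light, unadjusted). The camera calls numbered 12 of 23 lists in the dark and 15 after light, none of them with an estimated correlation. Across 19823 genes the ratios in the dark and after light correlated at r = 0.822.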

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

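The test of matched gene sets was written before its result was seen, and the tests on repeat 2 alone, on organelle reads between repeats and on small RNA genes were chosen afterwards. Camera on the interaction of light with the kind of library set 8 lists apart from all other genes at the preset correlation, none of them with an estimated correlation, and fry on the interaction, a test against no change, called 0 of them without the block (adjusted p = 0.264 for auxin response and 0.991 for the others) and auxin response with it (0.0295). Their median log2 differences were 0.62 for light-harvesting proteins, 0.17 for photosystem subunits, 0.37 for chlorophyll synthesis, 0.72 for the Calvin cycle, 0.32 for plastid ribosomal proteins, -0.44 for auxin response, 0.35 for plastid-encoded and -0.73 for mitochondrion-encoded genes.

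The median efficiency changes of the first 6 of these lists had the direction of their mRNA, which could arise if ribosome-protected libraries stretched every light response alike. Across 5578 abundant genes the efficiency change of a repeat did increase with the mRNA change of the other repeat, with slopes of 0.0849 and 0.0836. Against 10000 random sets matched on mRNA change and abundance, 5 of the 6 lists still lay further out than 95% of the sets. For light-harvesting proteins (0.62 against a matched median of 0.23) one-sided permutation gave p = 0.0013, and for chlorophyll synthesis (0.37 against 0.10) p = 0.0094. For the Calvin cycle (0.72 against 0.20) one-sided permutation gave p = 3.0e-04, and for plastid ribosomal proteins (0.32 against 0.07) p = 0.0020. For auxin response (-0.44 against -0.13) one-sided permutation gave p = 7.0e-04, while photosystem subunits were matched or passed by 8101 sets. The lists had been taken up on these same medians, and random sets lack the shared variation of genes within a list. The comparison therefore cannot decide on a common stretch, which stays open. The shallow ribosome-protected libraries of repeat 1 stay open as a source, since all 6 lists had the same sign in repeat 2 alone but had been taken up on values of both repeats. Calls on the Calvin cycle, chlorophyll synthesis, photosystem subunits and plastid ribosomal proteins were lost without the dark one of these libraries. Calls on the same lists were also lost without the dark mRNA library of repeat 2, which was not shallow. Without a block, such an omission brings the difference between repeats into the contrast. In the dark these lists were higher in repeat 2, by a median log2 of 0.98 to 1.83 in ribosome-protected reads and 0.52 to 1.73 in mRNA. The omissions therefore cannot tell depth apart from that difference. Without the light ribosome-protected library of repeat 1 the calls on all 6 lists were kept. Omission of single libraries turned the sign for photosystem subunits and plastid ribosomal proteins, which the difference between repeats can do by itself. Genes that vary together between libraries and, as a hypothesis, a light effect on translation of these genes stay open as well.

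Plastid-encoded genes had fewer mRNA reads in repeat 2 than in repeat 1, by a median log2 of -2.96 in the dark and -3.32 after light, with 3 of 80 genes higher in each condition. Fewer plastid transcripts in those seedlings would lower the ribosome-protected reads as well, but their median differed by -0.0030 in the dark and 0.45 after light, which argues against that. Less RNA without a poly(A) tail carried through purification in repeat 2 could also lower mitochondrion-encoded mRNA; its median differed by -0.76 in the dark and -0.62 after light, between the -1 that this explanation was set to need and the -0.5 above which it would have been excluded, so it cannot be told apart from other differences between the mRNA libraries. The repeats' biological difference, if any, was not tested. The efficiency values of plastid-encoded genes rest on these libraries.

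Reads in untranslated regions, outside the comparisons, numbered at least 20 in each ribosome-protected library and were at least 2-fold above the mRNA libraries per CDS read at 11 loci, with 0.5 reads added to each count and CDS counts under 3 in ribosome-protected libraries set to 3. As the smallest ratio between a ribosome-protected and an mRNA library, this was 406.8 in the 5′ leader of LAF3 (14348 to 35813 leader reads against 16 to 141 CDS reads per ribosome-protected library), 63.3 in AT4G23420, 50.05 in AT4G03410, 11.1 in AT3G24070 and 36.7 in the 3′ region of NUDX1, while it was at least 7.07 in the 3′ region of AT2G07774, with 0 to 1 CDS reads, and 2.13 to 5.16 at the other 5 loci (a lower bound in AT3G47965). AT3G55860, the locus next to LAF3, had 0 CDS reads in all libraries and so no such ratio, but 6976 to 19026 leader reads in the ribosome-protected against 15 to 301 in the mRNA libraries, a ratio of 274.1 or more after scaling to library totals. A gene for a tRNA, snRNA or snoRNA inside the locus is a candidate source, since 6 of the 11 loci overlapped one (an snRNA gene in AT4G23420, a tRNA gene in AT4G03410, NUDX1, AT2G07774 and CK1, an snoRNA gene in AT2G35750) against 116 of 18923 others (0.613%), an odds ratio of 192.7 (95% interval 48.5 to 808; Fisher's exact p = 2.85e-11). Of the 11 loci, LAF3, AT3G24070, AT3G47965, PK1 and AT4G03260 overlap none, nor does AT3G55860, and what their leader reads are stays open.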

How the results depend on the processing

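The blocks for each kind of library, the stricter filter with the block and DESeq2 with the block were tests chosen after the results were seen. In the order mRNA, ribosome-protected mRNA, efficiency, dark ratio and light ratio, edgeR called 947, 1355, 0, 923 and 487 genes. The counts stayed within 1.5 times with limma-voom (1319, 1165, 0, 848, 504), DESeq2's size factors (860, 1322, 0, 897, 387), no filter (964, 1396, 0, 739, 479), organelle genes left out (968, 1364, 0, 960, 500) and a minimum log2 change of 1 (940, 1338, 0, 908, 487). With the repeat as a block, for the pairing of samples, they were 6659, 6341, 0, 8004 and 6470, with a lower fitted spread (0.170 against 0.391). Simulated counts gave more false calls with the block than the threshold allows. The Wald test of DESeq2 gave 2234, 2690, 15, 2696 and 1724; the cause was not tested. A minimum of 50 reads in every group mean, which tests fewer genes, gave 547 for mRNA and 180 for the light ratio. The 4 libraries of a comparison alone, with fewer samples, gave 0 for mRNA, 634 for ribosome-protected mRNA, and 0 for the dark and for the light ratio in edgeR (3224, 3641 and 3341 unadjusted where 0). A separate block for each kind of library gave 7072 and 6554 (0 for efficiency, 1564 unadjusted), the stricter filter with the block 4630 and 4663 (0, 932 unadjusted), and DESeq2 with the block 6643, 6494 and 204. Omitting 1 library at a time, where a lone library is assumed to vary like the other groups and the repeats become unbalanced, gave 3 to 660 calls for mRNA, 176 to 1122 for ribosome-protected mRNA, 0 to 0 for efficiency (144 to 449 unadjusted), 0 to 0 for the dark ratio (3108 to 4456 unadjusted) and 0 to 276 for the light ratio. Camera called 13, 16 and 8 lists for mRNA, ribosome-protected mRNA and efficiency; with an estimated correlation 1, 1 and 0; and without single libraries 13 to 15, 16 to 17 and 6 to 13. Some lists turned their sign without 1 library, with adjusted p over the 8 omissions of 4.99e-04 to 0.654 (mRNA) and 2.26e-04 to 0.727 (ribosome-protected mRNA) for cytosolic ribosomal proteins, 1.59e-12 to 0.154 for plastid-encoded genes in mRNA, and in efficiency 3.79e-07 to 0.582 for photosystem subunits, 0.00350 to 0.346 for flavonoid genes, 8.15e-10 to 0.0275 for cytosolic ribosomal proteins, 6.98e-11 to 0.778 for plastid ribosomal proteins and 6.92e-26 to 0.0201 for plastid-encoded genes. Without a block, such an omission leaves 1 repeat in a group, so the difference between repeats enters the contrast. Cytosolic ribosomal proteins were higher in repeat 2 in every group, by a median log2 of 0.60 to 1.00. Plastid-encoded mRNA differed by -2.96 in the dark and -3.32 after light. For these lists the signs turned in the direction that this difference gives. Whether it accounts for every turn was not tested. Under the other settings 299 list results kept their side of the threshold, 36 lost a call and 4 gained one. Apart from the loss of expansins and XTHs with a separate block, the losses came with the estimated correlation. Of 97 calls on named genes, 97 stayed with the block and with DESeq2, 96 with limma-voom and without a filter, 94 with the size factors, 35 with the libraries of the comparison alone and 43 (without the dark mRNA library of repeat 1) to 60 (without the dark ribosome-protected library of repeat 1) with omissions, and 0 reversed. In the light responses the block changed no camera call on a list other than the clock in ribosome-protected mRNA (0.0414); a separate block for each kind of library lost expansins and XTHs (0.0543) and gained plastid-encoded genes (6.23e-05) in mRNA, and gained cytosolic ribosomal proteins (0.0395) and translation factors (0.0418) in efficiency. Fry called 8, 9, 0, 6 and 4 lists without and 15, 14, 1, 7 and 9 with the block. The 4617343 and 4843438 CDS reads of the ribosome-protected libraries of repeat 1 make efficiency less precise for genes of low abundance. The efficiency changes of the repeats correlated at 0.260 over all genes against 0.670 over abundant ones, and depth as the reason was not tested.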

Other observations

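The test of protein location was written before its result was seen, and DESeq2 with the repeat as a block was added after the results were seen. That fit called 204 genes in translational efficiency, 199 up and 5 down, where edgeR with the block called 0 (1233 unadjusted). All 204 had the same sign in both repeats, on which the calls themselves rest. In simulated data DESeq2 with the block made 28 false among 176 calls. That simulation had few changed genes and a repeat effect of the form that the block fits. Its share of false calls need not hold here. The genes named here were chosen after their values were seen. ALDH11A3, a non-phosphorylating glyceraldehyde 3-phosphate dehydrogenase, had an efficiency log2 change of 1.95 (DESeq2 adjusted p = 4.21e-20), ABCG7, a transporter, 1.88, AGY1, a SecA protein of the chloroplast, 1.74, GAPA1, of the Calvin cycle, 2.25, FAD6, a plastid desaturase, 2.01, CA2, a carbonic anhydrase, 2.60 (adjusted p = 1.82e-06), and LHCB3 1.37. The mRNA of ALDH11A3 and ABCG7 was fitted at 0.07 and -0.12, and their ribosome-protected reads at 1.99 and 1.74. The 5 lowered genes were AT1G72645 (-2.95), EEL (-3.49), IQD12 (-1.67), AT4G25280 (-0.97) and CPUORF47 (-1.44).

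Genes whose reference description places the protein in the chloroplast were tested as a group among nuclear genes with a described location. With members of the fixed lists left out, they made up 83 of 138 raised genes (60.1%) against 22.6% of 8833 genes, an odds ratio of 5.36 (95% interval 3.75 to 7.71; Fisher's exact p = 1.14e-21). With all genes it was 93 of 154 (odds ratio 5.34). Genes described as mitochondrial and not as chloroplast made up 0 of 154 (upper bound of the odds ratio 0.552, Fisher's exact p = 0.00321). Genes described as both were counted as chloroplast only, which favours the contrast between the groups. The descriptions are incomplete, since that of GAPA1, of the Calvin cycle, did not place it in the chloroplast. Camera on all 2516 chloroplast genes gave a p of 4.45e-06, and 0.219 with an estimated correlation. On the 576 mitochondrial genes outside the chloroplast group camera gave 0.503 and 0.770. Fisher's test treats genes as independent, and genes that vary together between libraries remain an open explanation, since the camera call was lost with an estimated correlation. The groups were also not matched on mRNA change or abundance, so a common stretch of light responses stays open here too.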
